A study of Homo sapiens with 4 samples.

How the data were processed

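Total RNA from H9 human embryonic stem cells was measured on 4 single-colour Illumina bead arrays, 2 from FGF2-starved and 2 from FGF2 re-stimulated cells. Per the labels' protocols, 300 ng of total RNA was linearly amplified with an in vitro transcription of 6 h and labelled with Cy3. BeadStudio 1.0 is named in the submitters' processing notes. The authors deposited, for each array, a mean bead intensity, a spread of the bead intensities and a detection score per probe, per the file headers. The intensities ranged from 72.5 to 62020.4 over the 4 arrays with no value below 0, so the deposited intensities were taken as neither background-subtracted nor scaled. The detection score, per the file headers and values, runs from 0 to 1 and is near 1 for bright probes. The series' value table holds the authors' processed intensities of the same arrays on a linear scale. Each of its columns was found to be a straight line of that array's deposited intensities, to within 0.10 intensity units. A constant of 124.5, 119.9, 118.7 and 115.8 had been subtracted and a factor of 0.941, 1.07, 0.944 and 1.07 applied on the starved and re-stimulated arrays of experiment 1 and then of experiment 2. Values were given exactly for the probes with a detection score over 0.99. The medians of the given values were 275.9, 310.1, 236.4 and 273.9 in that order. They are not centred, and how the factors were chosen is not given in the sources used here.

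Each array held 24350 probes named by a GI number, a sequence record identifier, and 4 control probes with the names of bacterial genes (lysA, pheA, thrB and trpF), which were used in the background step and left out of scaling and tests. Their signals lay between 116.4 and 130.8 on all arrays, and none was detected. Medians and 75th percentiles differed by 8.74% and 17.6% between the brightest and dimmest array, above the 5% set as the limit for leaving the arrays unscaled. Signals were therefore processed with limma 3.58.1 in R 4.3.3: normexp background correction with the background mean and SD inferred from the detection scores (taking 1 minus the score as a p-value), an offset of 16, and quantile normalization between the 4 arrays. Signals under 46.0, the median over arrays of the lowest normalized signal of a detected probe, were set to that floor (5.52 on the log2 scale) before taking log2. The offset and the floor shorten the fold changes of dim probes. A probe was called detected at a score over 0.99 and tested if detected on both arrays of at least 1 group, which 10886 probes (44.7%) were.

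Groups and experiment numbers came from the sample titles. The groups were compared with lmFit and eBayes (trend = TRUE), two-sided, with the experiment as a block, because the labels name the starved sample of the same experiment as each re-stimulated sample's control. Deviations of same-numbered arrays from their group means correlated at 0.35 across tested probes, and 127 probes differed between experiments in the same fit at an adjusted p under 0.05. The fit has 1 residual degree of freedom per probe and a prior of 13.0 degrees of freedom from all probes, so the tests rest largely on the pooled variance. The labels do not say whether the 2 experiments came from separate cultures. If they did not, the p-values measure only the spread between these samples. Array data have no read depth, and the number of arrays limits the precision. No test was made of values given once per array, such as the number of detected probes. For these, an exact permutation test of 2 arrays against 2 cannot reach a p under 0.05.

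The procedure was tested on simulated data: 20 simulated sets of 4 arrays, each with 200 changed probes and a median of 11483 probes tested, recovered 46.0% of the 1.5-fold, 88.4% of the 2-fold and 99.7% of the 4-fold changes in this comparison. On average 6.10% of the calls were false, with a range of 0 to 20.9% over the sets. With no change simulated, 4 of 20 sets gave calls, at most 2 each. The changed probes were drawn only from probes well above background, with equal numbers rising and falling. Recovery among the dimmest tested probes was therefore not measured. The noise was drawn from the variance model fitted to these arrays, which the test itself assumes. The low share of false calls is thus partly built in.

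The rule for named probes, the gene lists, the main tests and most alternatives were fixed before the data were examined. The rule took, in each direction, the 12 probes with the largest change among those past the threshold with the same sign in both experiments. Because no identifier was matched to a gene, only the first 2 in each direction are named. For the same reason 27 lists of pathway and cell type genes (518 genes) could not be matched to probes. Their tests, with camera and fry, were not run, and the brightest-probe rule for genes with several probes did not apply. Alternatives covered the scaling between arrays, the floor, the detection filter, the authors' values (with missing values at the lowest given), the block, the variance moderation, the threshold and leaving out arrays. Alternatives chosen after seeing the data were no background correction, normexp without detection scores at an offset of 50, no floor, quantile normalization within each experiment, and the correlation without the called probes. The groupings by signal, by probe class and by isoform pair were also chosen after the files were seen. The planned normexp with detection scores became the main setting, as the rule fixed beforehand required for signals without background subtraction. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.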

Results

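Transcript levels were measured in H9 cells, an established line of human embryonic stem cells, to describe how the cells responded when fibroblast growth factor 2 (FGF2) was returned after a period without it. FGF2 is a growth factor that is widely added to human embryonic stem cell cultures. In both groups the cells had been kept for 2 days in medium conditioned by mouse embryonic fibroblasts on a matrigel coating and then starved for 24 h without FGF2, in the presence of 30 uM SU5402, an inhibitor of FGF receptor tyrosine kinases. The FGF2-starved group was harvested after starvation. The FGF2 re-stimulated group was washed and given 40 ng/ml FGF2 in unconditioned medium for 4 h. Each group held 2 arrays, 1 from each of 2 experiments, and the labels name the starved sample of the same experiment as the control of each re-stimulated sample. The 4 single-colour bead arrays carried the same 24350 probes. The labels mention washing and fresh medium only for the re-stimulated cells, which were also cultured for 4 h beyond the starvation. The comparison thus covers the removal of SU5402, the medium change and the added time together with FGF2.

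Slightly fewer probes were detected after re-stimulation in both experiments. In experiment 1, 11048 probes (45.4%) were detected in starved cells and 10765 (44.2%) in re-stimulated cells. In experiment 2 the numbers were 11124 (45.7%) and 10609 (43.6%). The mean deposited signal of the re-stimulated array was 0.928 times that of the starved array in experiment 1 and 0.929 times in experiment 2, before any scaling between arrays. Whether the lower signal of these arrays gave the lower counts was not tested. After normalization, log2 signals correlated across tested probes at r = 0.987 between the starved arrays and 0.99 between the re-stimulated arrays, above the values of 0.975 and 0.98 between the starved and re-stimulated arrays of experiments 1 and 2. Probes are not independent replicates in these correlations.

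The main comparison asked which transcripts differed between FGF2 re-stimulated and FGF2-starved cells. Of 10886 probes that were detected on both arrays of at least 1 group, 821 (7.54%) were higher and 677 (6.22%) were lower after re-stimulation. Large changes were more often rises: 203 probes rose and 40 fell by at least 2-fold, and 28 rose and 2 fell by at least 4-fold. Of those 2 falls, that of probe GI_41406065-A was -0.21 on the log2 scale in experiment 1 and -5.36 in experiment 2. The median change was 1.65-fold among probes that rose (log2 change 0.73, interquartile range 0.57 to 0.996) and 1.49-fold among probes that fell (log2 change -0.57, interquartile range -0.69 to -0.47). Both medians cover called probes only, and falls were called most often among bright probes, where a small change was easier to call. All 1498 changed probes moved in the same direction in both experiments, and 1414 of them by at least 1.2-fold in each. The test itself favours such probes, since its residual is the difference between the 2 experiments' changes, so this agreement is largely fixed by the selection. These calls used limma with the experiment as a block and a Benjamini-Hochberg adjusted p under 0.05, with 2 arrays per group and a median standard error of 0.15 on the log2 scale. Comparing the groups without the block left 186 probes higher and 34 lower, and with any 1 of the 4 arrays left out, which rules out the block, limma called 0 probes, with 1311 to 2039 at an unadjusted p under 0.05. Doubling the floor on low signals also left 0 calls in limma, with 1715 at an unadjusted p under 0.05. The number of falls also depended on the scaling between arrays: 595 probes rose and 1160 fell with no scaling, against a share of rises of 54.8% in the main setting. With the authors' values, which differ in the scaling, the background step and the handling of undetected probes at once, 882 rose and 268 fell. Among the settings of background, scaling, floor, filter and fit that made calls, the number of rises of at least 2-fold ranged from 77 with no background correction (13 falls) to 344 with the authors' values (46 falls).

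**Figure D1:**
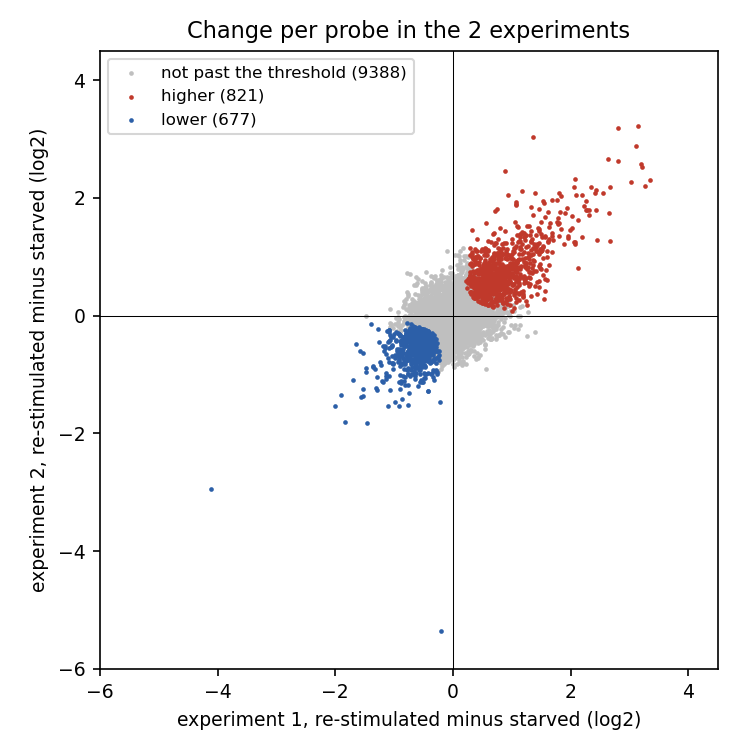
Change of each of the 10886 tested probes in experiment 1 (x axis) and experiment 2 (y axis), as the re-stimulated minus the starved log2 normalized signal; each point is a probe, coloured by whether it was higher, lower or not past the adjusted p threshold. The 821 higher and 677 lower probes, which the test selects in part for agreement between the experiments, lie in the quadrants where both moved the same way, and a single lower probe at the bottom moved by -0.21 in experiment 1 and by -5.36 in experiment 2, where its re-stimulated array was at the floor.

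**Figure D2:**
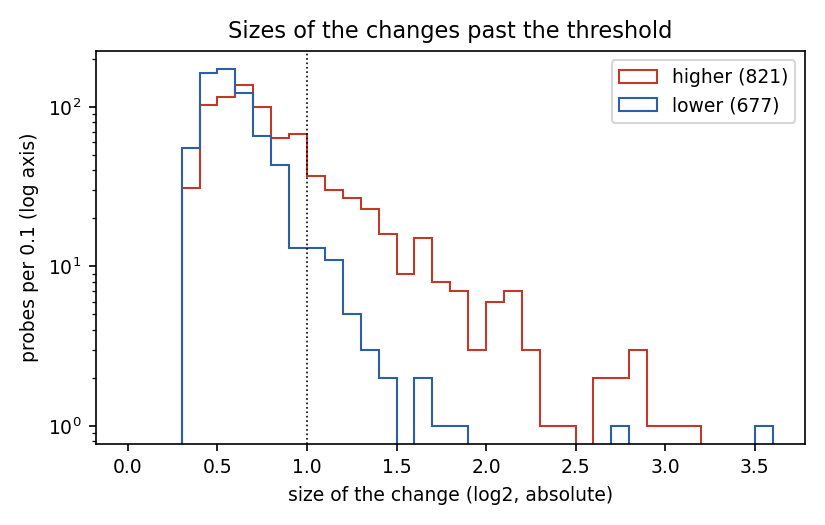
Number of probes past the threshold (y axis, log scale, per 0.1 of log2 change) against the absolute log2 change (x axis), for the 821 probes that were higher and the 677 that were lower. Beyond the dotted line at 2-fold lie 203 rises and 40 falls.

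Most changed probes were detected on all 4 arrays, as were most tested probes (9955 of 10886), so this share follows largely from the filter. Of the 821 probes that rose, 730 were detected on all 4 arrays, 56 were detected on 1 of the 2 starved arrays and 35 on neither. In all, 102 tested probes were detected on neither starved array. The rises of the 35 were lower bounds, with a median of at least 1.91-fold and a range of bounds from 1.56 to 4.95-fold. Of the 677 probes that fell, 616 were detected on all 4 arrays, 40 on 1 of the 2 re-stimulated arrays and 21 on neither. In all, 244 tested probes were detected on neither re-stimulated array. The falls of the 21 were at least 1.71-fold at the median, with bounds from 1.41 to 10.9-fold. A bound sets the brighter group's mean against the lowest signal among detected probes, or the probe's own signal where that was higher, on each array of the other group.

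Probes that rose and probes that fell were found at all expression levels. The tested probes were ordered by mean log2 signal over all 4 arrays and divided into 4 groups of equal size. From the dimmest to the brightest group, 7.46%, 7.13%, 7.90% and 7.68% of the probes rose, and 4.45%, 5.48%, 7.09% and 7.86% fell. With the authors' values the shares that fell were 1.69% in the dimmest and 3.42% in the brightest group, and with no scaling between arrays 4.59% and 16.6%. The median standard error was 0.18 in the dimmest and 0.11 in the brightest group on the log2 scale, so a small change was easier to call in a bright probe. Rises of at least 2-fold numbered 56 in the dimmest group and 37 in the brightest, and falls of that size 14 and 8.

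The probes of this array fall into 3 design classes, given by the last letter of the identifier. In Illumina's naming, S marks a probe for a gene with a single known transcript, A a probe shared by all isoforms of a gene, and I a probe for 1 isoform. Among S probes, 669 of 8959 tested rose and 567 fell. Among A probes, 104 of 1269 rose and 90 fell. Among I probes, 48 of 658 rose and 20 fell. The share that changed was 13.8% for S probes (exact binomial 95% interval 13.1 to 14.5), 15.3% for A probes (13.3 to 17.4) and 10.3% for I probes (8.12 to 12.9). These intervals treat probes as independent and cover counting error alone. The I probes were also dimmer, with a median log2 signal of 7.25 against 8.19 for S probes and 8.33 for A probes.

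The identities of the probes are given as the files give them, since the files pair no probe with a gene and the gene table used here matched 0 of the 24350 identifiers. The largest rise was that of GI_10047091-S, from a log2 normalized signal of 6.08 ± 0.13 (SD, n = 2) in starved cells to 9.26 ± 0.18 (SD, n = 2) in re-stimulated cells. This was a 9.10-fold rise (log2 change 3.19, SE 0.16, limma adjusted p = 4.99e-08), with 8.88-fold in experiment 1 and 9.32-fold in experiment 2. GI_31542304-S rose 8.0-fold (log2 change 3.0, SE 0.16, limma adjusted p = 5.08e-08), from 6.43 ± 0.20 to 9.43 ± 0.36 (SD, n = 2 per group), with 8.67-fold and 7.39-fold in the 2 experiments. Both probes were detected on all 4 arrays. The rises were smaller with no background correction (4.18-fold for GI_10047091-S and 4.17-fold for GI_31542304-S) and with normexp without detection scores (5.34-fold and 5.17-fold). Each passed the threshold in 13 of 18 tested alternatives, the exceptions being the doubled floor and the omission of any 1 of the 4 arrays. The folds there were 6.68 with the doubled floor and 8.41 to 10.04 with 1 array left out for GI_10047091-S, and 7.37 and 6.77 to 9.63 for GI_31542304-S, in fits whose prior had 0.828 (doubled floor) and 1.05 to 1.59 (1 array left out) degrees of freedom, against 13.0 in the main setting.

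The largest fall was that of GI_9790905-S, which was detected on both starved arrays, at deposited signals of 986 and 444.9, and on neither re-stimulated array, at 132.8 and 117.9. It was at least 10.9-fold lower after re-stimulation (limma adjusted p = 2.49e-07), with starved cells at 9.04 ± 0.82 (SD, n = 2) on the log2 scale. The bound was 16.7-fold in experiment 1 and 7.14-fold in experiment 2, and 7.29-fold without the starved array of experiment 1. The fitted fall of 11.5-fold, which depends on the floor, was 5.74-fold with the floor doubled, 18.7-fold with the floor at 0.5 times or left out, 4.26-fold with no background correction, 5.66-fold with normexp without detection scores, 7.34-fold without the starved array of experiment 1 and 11.9 to 16.6-fold without 1 of the 3 other arrays. It passed the threshold in 12 of 17 tested alternatives, again not with the doubled floor or with any 1 array left out. GI_41406065-A had the next largest fitted fall, with a log2 change of -2.78 (SE 0.70, limma adjusted p = 0.0173), but its 2 experiments were far apart. Its log2 change was -0.21 in experiment 1, where its deposited signal went from 3830.1 to 3111.2, and in experiment 2, where the signal went from 1945.5 to 103.9 and was not detected, it was at least 38.2-fold lower (log2 change -5.36 as set by the floor). The fitted change of -2.78 depends on that floor and was -3.32 without one, and -1.97 with no background correction. It was -5.84 without the re-stimulated array of experiment 1. Without the re-stimulated array of experiment 2 its log2 change was 0.22, with the opposite sign (limma adjusted p = 0.859). It passed the threshold in 8 of 17 tested alternatives. At the same log2 change of -2.78, the call was lost without the block, with eBayes without a trend and with robust eBayes (limma adjusted p = 0.398, 0.0872 and 0.639). The other exceptions were the authors' values, the doubled floor and the omission of any 1 array. Of all 1498 changed probes GI_41406065-A was the only 1 whose change differed by over 4-fold between the experiments, and 22 differed by over 2-fold.

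**Figure D3:**
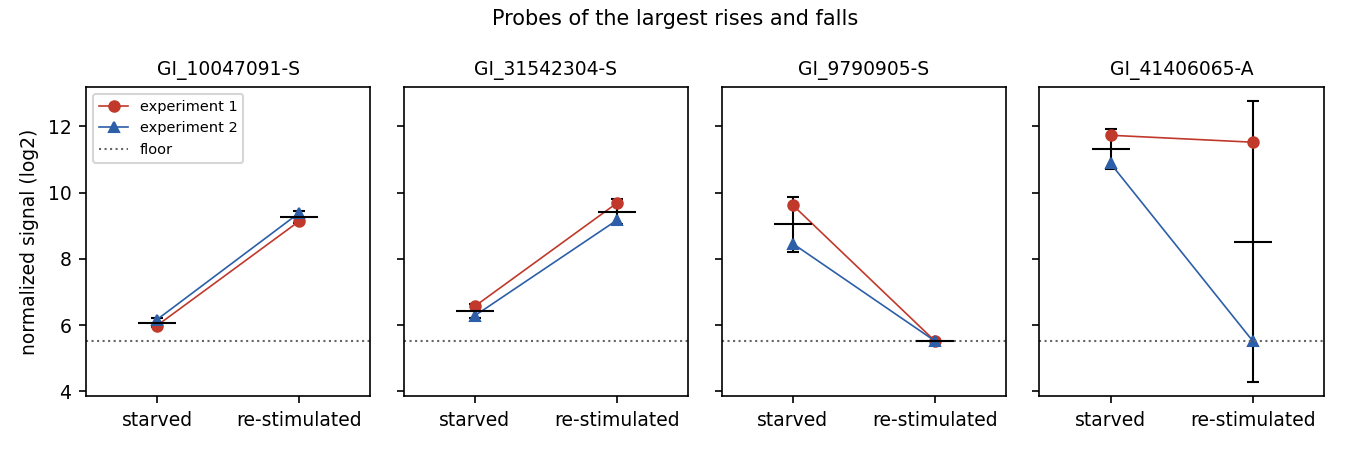
Log2 normalized signal (y axis) of the 2 probes with the largest rises and the 2 with the largest falls, in starved and re-stimulated cells (x axis); coloured markers joined by a line are the 2 arrays of an experiment, the black dash and bars are the group mean and SD (n = 2), and the dotted line is the floor set on low signals. The 2 rises were of like size in both experiments, GI_9790905-S moved by -4.10 in experiment 1 and -2.94 in experiment 2 with both re-stimulated arrays at the floor, and GI_41406065-A moved by -0.21 in experiment 1 and -5.36 in experiment 2 with its re-stimulated array there at the floor.

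The second comparison asked how far the 2 experiments showed the same response. They share no array, so chance on a control array does not link them. The labels do not say whether they share a culture, and chance in a shared culture would link them. Across the 10886 tested probes the log2 change in experiment 1 correlated with that in experiment 2 at Pearson r = 0.678 and Spearman rho = 0.564. The sign was the same for 7622 probes, 70.6% of those with a change other than 0 in both. A rise of at least 1.5-fold was seen in both experiments for 409 probes, against 47.1 for independent lists of 803 and 638 probes. A fall of that size was seen in both for 149 probes, against 23.5 for independent lists of 590 and 433. Only 4 probes changed by at least 1.5-fold in opposite directions. Among the 9388 probes that were not called, the sign was the same for 65.9%, with r = 0.318 and rho = 0.368. That set lacks the probes that the test selects for large changes alike in both experiments. Changes were somewhat larger in experiment 1: the median absolute log2 change of the called probes was 0.68 there and 0.60 in experiment 2, and 939 of the 1498 (62.7%) changed more in experiment 1. This difference between experiments has no test, since each experiment holds 1 array per group.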

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

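In the settings of background, scaling, floor, filter and fit that made calls, rises of at least 2-fold outnumbered falls. They were not counted at other thresholds. The settings below moved the counts of 821 higher and 677 lower probes, or the correlation of the experiments, beyond 1.5 times or their interval. Without the replicate block 186 probes were higher and 34 lower, all among the main calls. Leaving out any 1 array, with no block and the lone array assumed to vary like the other group, gave 0 calls in limma throughout (1311 to 2039 at an unadjusted p under 0.05). The lower count was 1160 with no scaling between arrays, 268 with the authors' values and 413 with eBayes without a trend. A floor at 2 times the main floor gave 0 higher and 0 lower (1715 at an unadjusted p under 0.05), with a prior of 0.828 degrees of freedom. Without a detection filter 1515 were higher and 1506 lower, but more than 50% of the residual variances were then 0 and limma warns that its moderation is unreliable. At an adjusted p under 0.10 the lower count was 1064, and at 0.01 the counts were 469 and 210. At 1.5-fold in both experiments, with no test, they were 409 and 149. Pearson r was 0.701 with the floor at 2 times, 0.664 without the filter (rho 0.459), 0.664 with the authors' values, 0.711 with no background correction, 0.702 with normexp without detection scores, and 0.318 with the called probes left out (rho 0.368). The same-sign share was 73.5% with no scaling, 69.7% with the authors' values and 65.9% with the called probes left out. The log2 change of GI_41406065-A ranged from -5.84 to 0.22 with 1 array left out, with the changed sign without the re-stimulated array of experiment 2, and passed the threshold in 8 of 17 tested alternatives. The 3 other named probes kept their direction in the alternatives run, but not their size: log2 changes ranged from 2.06 to 3.63 for GI_10047091-S, 2.06 to 3.36 for GI_31542304-S and -4.22 to -2.09 for GI_9790905-S, smallest with no background correction. They passed the threshold in 13 of 18, 13 of 18 and 12 of 17 tested alternatives, and not with the floor at 2 times or with any 1 array left out. Rises and falls of at least 2-fold (203 and 40) numbered 344 and 46 with the authors' values, 141 and 17 without the block, 166 and 26 among probes detected on all 4 arrays, 77 and 13 with no background correction and 123 and 16 with normexp without detection scores. All other settings kept both main counts within 1.5 times. Leaving out an array removes arrays by construction. The counts move with the adjusted p threshold by definition. Leaving out the called probes removes those that the test selects for large changes alike in both experiments. For the remaining settings the cause was not tested. Gene list tests were not run, for want of gene names.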

Other observations

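All-isoform and isoform-specific probes that carry the same identifier offer a view of single transcripts within the response. Of 732 such pairs on the array, 105 had both probes tested. Their log2 changes correlated across pairs at r = 0.538 and rho = 0.644. In 7 pairs both probes changed, each time in the same direction, in 21 pairs only 1 of the probes passed the threshold, and in 77 neither did. A limma test of the difference of changes within the pair, with the experiment as a block, found 2 pairs that differed at an adjusted p under 0.05, and 4 at an unadjusted p under 0.05.

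In the paragraphs that follow, the tests by starved level, without a floor, with other background steps, of the scaling, of the level on the 3 brightest arrays and of a lost probe were chosen only after the result was seen; those by the dimmer group, of brightness and of detection in the pairs were fixed first.

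More probes rose than fell by at least 2-fold, 203 against 40. Shortening of falls by the floor and the background step was first tested on 6451 probes whose dimmer group lay at least 4 times above the floor (83.9% rises, exact 95% interval 74.8 to 90.7), but that filter drops falls that end near the floor and decides nothing. Among the 6733 probes at least 4 times above the floor in starved cells, from where a 2-fold fall stays above it, 78 called changes of 2-fold or more were rises and 25 falls, 75.7% (66.3 to 83.6), above the 60% set as the highest share under that explanation, while at 8 times above the floor the numbers were 44 and 17, 72.1%, with an interval (59.2 to 82.9) that reaches 60%. With no floor 242 rose and 52 fell by at least 2-fold, 82.3% rises (77.5 to 86.5), which argues against the floor alone as the cause. The share was 85.6% (76.6 to 92.1) with no background correction and 88.5% (82.0 to 93.3) with normexp without detection scores. Background left in, or an offset, also shortens the changes of dim probes, so these 2 settings cannot decide on the background step. A part of the floor and the background step in the split stays open. The scaling between arrays was tested by the lowest share over the other scalings, 77.8% with no scaling (168 rises and 48 falls, interval 71.6 to 83.1). This argues against the scaling as the cause of the split of large changes, although it moved that of small ones. All intervals in this paragraph treat probes of the same 4 arrays as independent and cover counting error alone. No biological explanation was tested.

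Re-stimulated arrays were dimmer than starved ones in both experiments. If 1 brightness factor per array were the cause, bright and dim probes would shift alike. Among 8609 probes detected on all 4 arrays and not called, the median log2 ratio of re-stimulated to starved background-subtracted signal was -0.13 in the dimmest and -0.13 in the brightest of 3 equal groups in experiment 1, and -0.11 and -0.16 in experiment 2. The larger gap between those groups was -0.049, just within the limit of 0.05 set in advance, so a single factor per array is a candidate explanation. The authors' factors were 1.14 times (0.19 on the log2 scale) and 1.13 times (0.18) higher for the re-stimulated array than for its starved control. These steps exceed the shifts just given, and the median change of all tested probes was 0.04 with the authors' values against -0.04 with quantile normalization. A true, even fall of most transcripts would give the same shift and was not tested, so the number of falls (677, or 1160 with no scaling) stays tied to the scaling.

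Both isoform pairs that differed (100%, exact 95% interval 15.8 to 100%) held a probe not detected on all arrays, which decides nothing, since a fall can itself end detection. The probes of the pair of GI_41406065-A lay at 10.88 or higher on the log2 scale on their 3 brightest arrays, over 8 times the floor (8.52), which argues against dimness there. In the other pair the lowest such signal was 5.54, against a floor of 5.52. Its all-isoform probe was detected on 2 arrays and changed by -1.225, so that signal can follow from the fall itself and decides nothing. In starved cells that probe averaged 6.75, and dimness stays open. In 1 of the 2 pairs the probes differed by under 0.5 on the log2 scale in 1 experiment (-0.21 in experiment 1 and -5.30 in experiment 2, as set by the floor), which is the pair of GI_41406065-A, and the other pair differed in both (-1.71 and -0.69), but near the floor this leaves a lost signal open there. For GI_41406065-A a fault in the reading of this 1 probe in experiment 2 is a candidate cause. Its bead spread there was 18.7% of its signal on the starved and 9.43% on the re-stimulated array. The medians for probes of like brightness were 2.62% and 4.75%. Of 4563 probes at least 8 times above the floor on 3 or more arrays, it alone was not detected on the remaining array. Its isoform-specific partner changed by -0.03. These values cannot tell such a fault from a change in the samples of experiment 2. No biological explanation was tested for these pairs.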
